A study of Drosophila melanogaster with 12 samples.

How the data were processed

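RNA from Kc167 cells, a Drosophila cell line of embryonic origin, was measured on Affymetrix Drosophila arrays. The 12 arrays fall into 4 groups of 3: cells alone (control), cells with PTIP knockdown, cells with knockdown of Pc and ph (Pc/ph), and cells with knockdown of Pc, ph and PTIP (Pc/ph+PTIP). Per the labels, 1000000 cells per well of a 6-well plate received 15 µg of double-stranded RNA (dsRNA), 5% serum was added after 1 hour and the cells were cultured for 6 days. The labels give no dsRNA for the control, and whether the control cells received any is not given in the sources used here.

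The deposited values are log2 RMA signal intensities, 1 per probe set and array. Per the submitters' processing notes the values were made with RMA and tested with limma, and the versions used are not given in the sources used here. The values were used as deposited. Of 18952 probe sets, 183 control probe sets were set aside and 18769 were tested. The platform annotation gives 13647 of these 1 gene symbol, 402 several symbols and 4720 no symbol. The gene table (assembly Release 6 plus ISO1 MT) was used for names and for neighbouring genes only, and no coordinates are printed. By gene number 13544 of the probe sets with 1 symbol matched it and 103 did not, and 0 symbols changed. For work on genes, 1 probe set per gene was kept, the one with the highest mean over all 12 arrays, which gave 11982 genes. A transcript that this platform does not measure under 1 symbol was not analysed here.

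Groups were compared in limma 3.58.1 under R 4.3.3 with 1 fit of the 4 group means to all 12 arrays, 8 residual degrees of freedom, moderated variances without a trend, and Benjamini-Hochberg adjustment over the 18769 probe sets within each comparison. A probe set was called at an adjusted p under 0.05. The 6 comparisons are PTIP against control, Pc/ph against control, Pc/ph+PTIP against control, against Pc/ph and against PTIP, and the interaction, which is the PTIP effect in Pc/ph cells minus that in control cells. Errors are standard errors (SE) of the fit unless an SD is stated, and n is 3 arrays per group. The limma and camera tests are two-sided.

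The replicate numbers were checked for pairing. The correlation between same-numbered arrays, after removing the group means, ran from 0.489 to 0.880 over 18 pairs, and for 9 of the 12 arrays the closest partner in another group carried the same number. For numbers 2 and 3 it was 0.489 to 0.775 between arrays of the same number and 0.396 to 0.784 between number 2 and number 3 of other groups. The replicate 2 minus replicate 3 differences correlated between groups at -0.250 to 0.242. The values thus show a replicate 1 batch and no pairing of numbers 2 and 3. The first principal component, with 68.1% of the variance, parts the replicate 1 arrays of all 4 groups from the other 8. A fit with the replicate number as a further term, called the replicate block below, was therefore run beside the fit without it, with the same differences, 6 residual degrees of freedom and its own SE. It was listed as an alternative, and the fit without it supplies the stated calls. Replicates 2 and 3 were also fitted alone, and replicate 1 was compared with them by sign, since it holds 1 array per group and allows no test of its own. Nothing in the sources used here says that replicates came from separate cultures, so the p-values measure the spread between these arrays. The number of arrays limits the precision.

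Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 19 lists within a comparison, and again with an estimated correlation. The lists cover Hox genes, Polycomb-target developmental regulators, Polycomb group genes, Trithorax group and SET1/MLL-type complex genes, Notch, JAK/STAT and ecdysone response genes, hemocyte, neuronal, muscle, germline, fat body and epithelial markers, humoral immunity, RNA interference, cell cycle, DNA damage, apoptosis and stress, and ribosomal protein genes. The knocked-down genes and the Y-linked genes, the latter a background reference in this female line, were described without a list test. Members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone.

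The genes named for a comparison are the 12 largest positive and 12 largest negative changes among genes with 1 symbol that pass the threshold and whose 3 arrays in 1 group all lie beyond the 3 of the other group, a condition not used for the interaction. Added to these are the knocked-down genes, the Hox genes, and up to 2 rising and 2 falling members of each list. Symbols that are only gene numbers count among the 12 and are mostly left out of the text. The same rule was applied to the calls with the replicate block. The tests, lists and this rule were fixed before the data were examined.

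Further quantities were computed for sets of probe sets. The genes that rise after Pc/ph knockdown were picked in fits that left out 1 Pc/ph and 1 control array, in 9 combinations, and measured on the arrays left out. Effects on independent arrays were correlated across probe sets, which are not independent replicates, so no p-value is given. Shared calls against the same controls were set beside 100 simulations of unchanged groups.

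The fits were tested on simulated data with the same number of probe sets, of which 200 each were changed by 0.5, 1 and 2 on the log2 scale. For PTIP against control, the fit without the block recovered 2.0, 42.0 and 84.0% of these and the fit with the block 69.0, 96.5 and 99.5%. For the interaction the shares were 0.5, 18.5 and 69.5% without the block and 35.0, 80.5 and 99.5% with it. Unchanged probe sets made up 4.23 to 5.47% of the calls with the block over the 6 comparisons. The simulated arrays had normal errors and a replicate offset equal in all groups, which is what the fit with the block assumes. These shares therefore do not show how that fit performs on the real arrays, where the offset may differ between groups. A list raised by 0.5 was called in each of the 6 comparisons, with 0 or 1 other list of 19. The simulated errors were drawn independently for each probe set. These list calls therefore do not show how often lists whose genes vary together are called wrongly.

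The alternatives tried are the replicate block, each array left out in turn, quantile and cyclic loess normalization of the deposited values, the upper range of mean values only, a variance trend, array weights, 1 probe set per gene, fits to the 6 arrays of a comparison, replicates 2 and 3 only, a batch term for replicate 1, and an estimated correlation in the list tests. The fits to replicates 2 and 3 only, those with the batch term and those that join the replicate block with another choice were chosen after the data were seen. Leaving out an array can leave 2 arrays in a group, whose spread is then taken to be that of the other groups. Without the block it also unbalances the replicate 1 batch between the groups, so part of the batch difference can enter the comparison. Calls lost and directions turned in such fits, for genes and lists, thus do not measure the noise of the group differences alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.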

Results

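Transcript levels were measured on 12 arrays from Kc167 cells, with 3 arrays each of cells alone, PTIP knockdown, Pc/ph knockdown and Pc/ph+PTIP knockdown. PTIP is a BRCT-domain protein of histone H3 lysine 4 methyltransferase complexes, and Pc and ph are subunits of Polycomb repressive complex 1. The series asks how PTIP bears on Polycomb-mediated repression. Array medians lay between 5.62 and 5.77 on the log2 scale for the replicate 1 arrays of the 4 groups and between 5.83 and 5.88 for the other 8. Upper quartiles were 8.65 to 8.95 and 9.62 to 9.74. The 9 probe sets of Y-linked genes, which this female line lacks, had array medians of 4.34 to 4.84 and highest values of 5.11 to 5.57, a range that serves as background.

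Pc was depleted in all 3 Pc/ph arrays, with log2 differences from the same-numbered control of -2.20, -2.49 and -2.30, or 21.8, 17.8 and 20.3% of its control level. In the Pc/ph+PTIP arrays Pc stood at 45.5, 65.9 and 70.9% of control, with differences of -1.14, -0.60 and -0.50. Its fitted change was -2.33 ± 0.62 (SE, n = 3) in Pc/ph cells, which limma did not call without the replicate block (adjusted p = 0.494) and called with it (adjusted p = 2.51e-04). Between Pc/ph+PTIP and Pc/ph cells Pc was higher by 1.59, called with the block (adjusted p = 0.00208) and not without it (adjusted p = 0.995). In PTIP cells the Pc differences were -0.66, 0.31 and 0.16. Levels of ph-p and ph-d were not analysed here.

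Ptip itself differed from the same-numbered control by -0.72, -0.19 and -0.44 in PTIP cells, which is 60.6, 87.8 and 73.5% of control. In Pc/ph+PTIP cells the differences were -1.01, -0.46 and 0.15, so the array labelled Pc/ph+PTIP replicate 3 lay above its control. Pc/ph cells, which received no PTIP dsRNA, gave -0.19, -0.51 and 0.03. The fitted Ptip changes of -0.45 in PTIP and -0.44 in Pc/ph+PTIP cells (SE 0.31, n = 3) were not called by limma. Nor were they called under the replicate block, where the SE was 0.21 (adjusted p = 0.296 and 0.339). In replicates 1, 2 and 3 Ptip stood at 7.15, 8.06 and 8.41 in Pc/ph+PTIP cells and at 7.97, 8.01 and 8.29 in Pc/ph cells. Between these groups it was thus lower in replicate 1 only. The fitted difference of -0.22 ± 0.31 was not called by limma, nor was it with the block (SE 0.21, adjusted p = 0.749).

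PTIP knockdown against control asks which transcripts depend on PTIP where Polycomb is present. Drat, a dehydrogenase-like regulator of cell death, rose by 2.95 ± 0.46 on the log2 scale (SE, n = 3; adjusted p = 0.0337). Genes that rose with it were rau, a Ras-association adaptor, by 2.08 ± 0.26, the glycine N-methyltransferase gene Gnmt by 1.76 ± 0.19 and ATPsynepsilonL by 1.69 ± 0.29. Smaller rises were found for the germline regulator tut (1.25 ± 0.16), the septate junction gene Lac (1.20 ± 0.18), the cell cycle regulator gnu (1.08 ± 0.16), gNacalpha (1.01 ± 0.17) and the Ryk-family receptor gene dnt (0.76 ± 0.13). Among the falls, the UDP-glycosyltransferase genes Ugt37D1, Ugt35C1 and Ugt302C1 changed by -2.69 ± 0.28, -2.36 ± 0.30 and -2.02 ± 0.27. The aminotransferase genes Oat and Bcat changed by -2.26 ± 0.19 (adjusted p = 0.00464) and -1.98 ± 0.25. The tubulin-binding protein gene ringer changed by -1.84 ± 0.23, the neuropeptide receptor gene Dh44-R2 by -1.83 ± 0.30, JhI-26 by -1.63 ± 0.25 and the leucine-rich repeat gene wdp by -1.58 ± 0.25. With the replicate block further genes passed, with rises in Phk-3 (2.06 ± 0.22), amd (1.88 ± 0.31) and Cyp12d1-d (1.81 ± 0.34), and the Hox gene Dfd rose by 0.39 ± 0.10 (adjusted p = 0.0397, and 0.866 without the block). Falls that passed with the block were Cyp28d1 (-3.32 ± 0.66), CBP (-3.28 ± 0.73), GstE9 (-2.89 ± 0.45), Cyp6d5 (-2.69 ± 0.41), Cyp28a5 (-2.57 ± 0.22), Ugt37C2 (-2.55 ± 0.59), Ugt317A1 (-2.46 ± 0.35), Aldh7A1 (-2.46 ± 0.49) and Cyp6a23 (-2.35 ± 0.45).

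In PTIP cells limma called 51 probe sets, 14 higher and 37 lower, and 773 had an unadjusted p under 0.05. The replicate block raised this to 1224, 511 higher and 713 lower, of which 259 changed at least 2-fold (50 higher, 209 lower), and all 51 were among them. Replicates 2 and 3 alone gave 2630 calls, 1515 higher and 1115 lower, of which 74.5% had the same sign in replicate 1. After quantile normalization the split was 196 higher and 269 lower, or 42.2% higher against 27.5% as deposited. The count was 9, 0 and 0 without control replicates 1, 2 and 3 (605 and 635 probe sets at an unadjusted p under 0.05 for the latter 2) and 25, 33 and 1 without PTIP replicates 1, 2 and 3. It was 26 and 25 without Pc/ph replicates 2 and 3, and 80, 26 and 26 without Pc/ph+PTIP replicates 1, 2 and 3. Of the 24 genes named without the block, 0 kept their call in every such limma fit. These fits have no block and leave the replicate 1 batch unbalanced between the groups. With the block, leaving out single arrays gave 475 to 1699 calls.

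Cell cycle and DNA replication genes were shifted upward in PTIP cells (26 genes, median 0.30, adjusted p = 8.20e-06). The shift was not called with an estimated correlation (adjusted p = 0.963 with an estimated correlation). None of its members passed without the block, 6 rose with it and 14 when adjusted over the list alone, among them CycB by 0.49 and Mcm6 by 0.58. Hemocyte markers were shifted downward (36 genes, median -0.14, adjusted p = 1.80e-04; adjusted p = 0.963 with an estimated correlation), and with the block 8 fell, 13 adjusted over the list alone, including the phagocytosis receptor gene eater (-1.68) and Glt (-1.70). Apoptosis and stress genes were shifted downward too (20 genes, median -0.28, adjusted p = 3.15e-05; adjusted p = 0.113 with an estimated correlation). With the block 5 of them fell and 0 rose, against 8 and 2 adjusted over the list alone, with ImpL2 at -1.50 and the small heat shock gene Hsp26 at -0.50. DNA damage and repair genes were lower (22 genes, median -0.25, adjusted p = 0.00802; adjusted p = 0.963 with an estimated correlation), and with the block 5 fell, among them the polymerase genes PolZ1 (-0.76) and PolQ (-0.53), and Corp rose by 1.09. Adjusted over the list alone, 11 of them fell and 2 rose. This last list was not called without PTIP replicate 1 (adjusted p = 0.473), in the upper range of mean values (0.0684) or in replicates 2 and 3 only (0.382). Ribosomal protein genes were called higher (36 genes, median 0.06, adjusted p = 0.0468; adjusted p = 0.963 with an estimated correlation), but not with the block (adjusted p = 0.0698), in the upper range of mean values (0.0626) or after cyclic loess (0.162). That call was also lost without control replicate 2 (0.966), control replicate 3 (0.999), Pc/ph replicate 3 (0.0505) and Pc/ph+PTIP replicates 1, 2 and 3 (0.0586, 0.0525 and 0.0551), and without PTIP replicate 1 its direction turned (0.473).

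Pc/ph knockdown against control asks which genes are released when Polycomb repressive complex 1 is lost. The largest rises were in Esp, a sulfate transporter family gene, by 5.44 ± 0.27 (SE, n = 3; adjusted p = 6.72e-06), the homeobox gene cad by 4.79 ± 0.21 (adjusted p = 2.75e-06), the BTB transcription factor gene rib by 4.52 ± 0.25 (adjusted p = 1.40e-05) and the GATA factor gene pnr by 3.998 ± 0.17 (adjusted p = 2.75e-06). In control cells cad averaged 5.21 ± 0.08 (SD, n = 3) and pnr 5.38 ± 0.21, within the range of the Y-linked probe sets, and in Pc/ph cells they averaged 10.004 ± 0.24 and 9.38 ± 0.15. Background limits the size of such rises, and so the order of these 4 genes. Further rises were found for the head homeobox gene oc (2.69 ± 0.41 SE), the endosome adaptor gene nuf (2.52 ± 0.27), the homeotic regulator tsh (2.31 ± 0.29), the arginine kinase gene Argk1 (2.02 ± 0.33), the zinc-finger gene disco-r (1.996 ± 0.16) and Psc (1.92 ± 0.25), itself a Polycomb repressive complex 1 subunit. The control means of oc (5.36), tsh (5.45) and disco-r (5.14) lie in the Y-linked range as well, so the same limit holds for them. Among the falls were the cystathionine beta-synthase gene Cbs (-3.21 ± 0.29, adjusted p = 8.30e-04), Ugt37D1 (-1.77 ± 0.28), the glycogenin gene Gyg (-1.49 ± 0.20) and the transporter gene out (-1.47 ± 0.23). Kank (-1.39 ± 0.21), the maltase gene Mal-A5 (-1.26 ± 0.13), the kinase gene Mos (-1.005 ± 0.13), the oxidative stress sensor Keap1 (-0.997 ± 0.16) and the piRNA pathway gene cuff (-0.88 ± 0.14) fell as well. Under the block Optix (2.72 ± 0.44), the secreted growth factor gene Idgf2 (2.54 ± 0.49) and wake (2.41 ± 0.38) also rose, and Dh44-R2 (-1.68 ± 0.30) and Kal1 (-1.64 ± 0.28) fell.

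**Figure D1:**
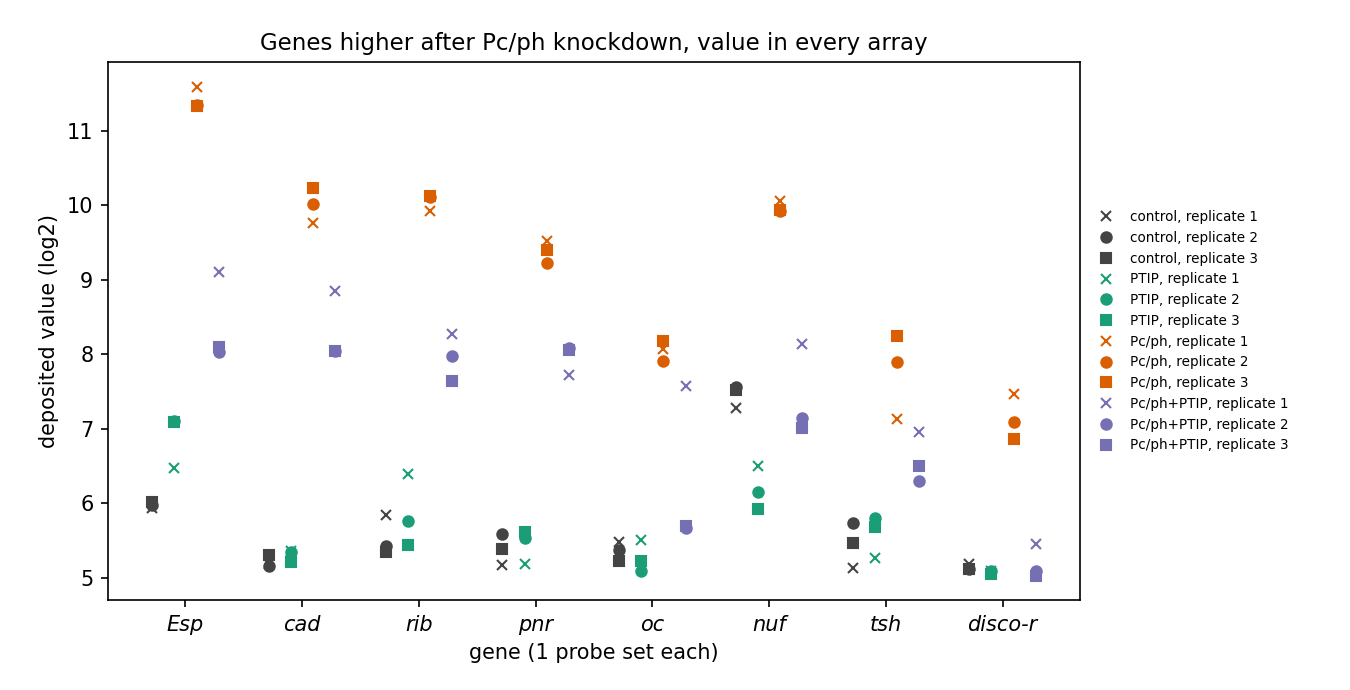
Deposited log2 value of 8 genes that rose after Pc/ph knockdown in every array, with colour for the group and marker for the replicate. The cad mean was 5.21 in control, 5.30 in PTIP, 10.004 in Pc/ph and 8.31 in Pc/ph+PTIP cells.

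Limma called 37 probe sets in Pc/ph cells, 23 higher and 14 lower, and 429 had an unadjusted p under 0.05. With the replicate block there were 287, 133 higher and 154 lower, with 119 changed at least 2-fold (69 higher, 50 lower), and all 37 were among them. In replicates 2 and 3 alone 1099 passed, 475 higher and 624 lower, and 84.3% of these had the same sign in replicate 1. The share of calls that were higher was 62.2% as deposited, 50.6% after quantile normalization (41 higher, 40 lower) and 51.1% after cyclic loess (46 higher, 44 lower). Leaving out an array gave 22 and 23 calls without control replicates 2 and 3, 56 without PTIP replicate 1, and 21 and 20 without Pc/ph replicates 2 and 3. Of the 24 named genes 10 kept their call without any single array, among them Esp, cad, rib, pnr, nuf, disco-r, Cbs and Mal-A5, and the fewest, 11, kept it without Pc/ph replicate 3.

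Polycomb-target developmental regulators were shifted upward in Pc/ph cells (107 genes, mean 0.33, median 0.03, adjusted p = 1.37e-11). The shift was not called with an estimated correlation (adjusted p = 0.127 with an estimated correlation), and it was called with the replicate block (adjusted p = 1.75e-05). Of its members 6 rose and 0 fell, and 12 rose adjusted over the list alone, with pnr and cad at the top and peb (1.84) and disco (1.87) below them. With the block 16 rose, and 19 rose and 1 fell adjusted over the list alone, with mirr at 2.13 and bab2 at 2.01 among those gained. Among the 4 Hox genes measured Dfd rose by 1.44 ± 0.15 (adjusted p = 0.0023), and pb, Scr and Antp did not pass, with Antp at 0.47 to 0.95 on 2 of its probe sets and at -0.07 on another. The Antp difference of 0.95 was 1.78 in replicate 1 and 0.53 in replicates 2 and 3. Control values of that probe set (5.51, 4.83 and 5.055) lay near the Y-linked probe sets. In every array pb (4.49 to 5.12) and Scr (4.43 to 5.07) lay in the range of the Y-linked probe sets. They thus gave no signal above background in any group, though both are members of the list tested. The Hox list was called higher (median 0.44, adjusted p = 9.62e-04; adjusted p = 0.0689 with an estimated correlation), but not with the block (adjusted p = 0.0552) or after cyclic loess (0.0698). Values for lab, Ubx, abd-A and Abd-B were not analysed here. In the list of 24 Polycomb group genes Psc rose and, with the block, Pc fell, and the list as such was not called (adjusted p = 0.542).

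Hemocyte markers were shifted upward after Pc/ph knockdown (median 0.13, adjusted p = 9.62e-04; adjusted p = 0.907 with an estimated correlation), with 0 members past the threshold without the block at limma's adjusted level. With the block NimB5 (1.28) and He (1.36) rose while SPARC (-0.46), vkg (-0.97) and Col4a1 (-0.95) fell, and 7 rose and 4 fell adjusted over the list alone. Epithelial and imaginal disc markers were higher (19 genes, median 0.16, adjusted p = 0.00234; adjusted p = 0.0689 with an estimated correlation), with the EGF receptor antagonist gene aos rising by 0.79 with the block and 4 rising and 1 falling adjusted over the list alone. Humoral immunity genes were higher (25 genes, median 0.05, adjusted p = 0.0048; adjusted p = 0.647 with an estimated correlation), with 1 rise in PGRP-LA (1.38, adjusted p = 0.0051) and 3 adjusted over the list alone, and with the block 2 rises and 1 fall. They were not called with the block (adjusted p = 0.124), after cyclic loess (0.0708) or in replicates 2 and 3 only (0.136). Without Pc/ph replicate 1 these 3 lists were not called, at adjusted p = 0.0875, 0.136 and 0.136, and the hemocyte list was not called in the upper range of mean values (0.0577). DNA damage and repair genes were called lower with the block (median -0.11, adjusted p = 0.0135; adjusted p = 0.764 with an estimated correlation) and not without it (adjusted p = 0.0733), and were also called with all probe sets of the members (0.0379) and after cyclic loess (0.00981). That list passed without control replicate 3 (0.0266), Pc/ph replicate 2 (0.0374) and Pc/ph replicate 3 (0.0205).

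Pc/ph+PTIP knockdown against control asks what remains of both responses when all of these genes are targeted together. CNMa, which encodes a neuropeptide, rose by 4.48 ± 0.38 (SE, n = 3; adjusted p = 0.00158), from a control mean of 5.64 ± 0.14 (SD, n = 3) to 10.12 ± 0.90. Genes of the Pc/ph response rose here too, with cad at 3.10 ± 0.21, pnr at 2.57 ± 0.17, rib at 2.43 ± 0.25 and Esp at 2.43 ± 0.27. Genes of the PTIP response that rose were Drat (2.83 ± 0.46), rau (2.31 ± 0.26) and ATPsynepsilonL (1.84 ± 0.29). The pherokine gene Phk-3 rose by 2.90 ± 0.36, the Notch glycosyltransferase gene fng by 2.57 ± 0.29 and the vitamin transporter gene Smvt by 2.25 ± 0.30. Ugt37D1 (-3.13 ± 0.28), Ugt35C1 (-1.97 ± 0.30), Ugt302C1 (-1.73 ± 0.27), Oat (-1.71 ± 0.19), Bcat (-1.61 ± 0.25), the glutathione transferase gene Mgstl (-1.57 ± 0.18), JhI-26 (-1.55 ± 0.25) and wdp (-1.49 ± 0.25) fell. Dfd rose by 1.09 ± 0.15 (adjusted p = 0.0157), and the other Hox genes measured did not pass. Under the block Idgf1 (3.002 ± 0.47) and bero (2.39 ± 0.45) also rose, and Cyp28d1 (-3.33 ± 0.66), GstE9 (-2.98 ± 0.45), Cyp6d5 (-2.75 ± 0.41), Cyp9c1 (-2.15 ± 0.40) and Cyp12a5 (-2.12 ± 0.45) fell.

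Against control, limma called 51 probe sets in Pc/ph+PTIP cells, 23 higher and 28 lower, with 730 at an unadjusted p under 0.05. The replicate block gave 1046, 509 higher and 537 lower, with 235 changed at least 2-fold (74 higher, 161 lower), and all 51 were among them. In replicates 2 and 3 alone the count was 2205, 1223 higher and 982 lower, with 83.4% of the same sign in replicate 1. After cyclic loess 110 were higher and 252 lower, or 30.4% higher against 45.1% as deposited. The count was 24, 17 and 10 without control replicates 1, 2 and 3, 103, 34 and 26 without PTIP replicates 1, 2 and 3, and 29 and 28 without Pc/ph replicates 2 and 3. It was 26, 18 and 18 without Pc/ph+PTIP replicates 1, 2 and 3. Of the 24 named genes 8 kept their call without any single array, namely CNMa, cad, pnr, fng, rib, Esp, Ugt37D1 and Mgstl.

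In Pc/ph+PTIP cells the cell cycle list was higher than in control (median 0.33, adjusted p = 3.46e-07; adjusted p = 0.709 with an estimated correlation), with 5 members rising under the block, 16 adjusted over the list alone, including CycB (0.48) and Mcm6 (0.55). Epithelial and disc markers were higher (median 0.18, adjusted p = 1.61e-04) and were called with an estimated correlation as well (adjusted p = 0.0428 with an estimated correlation, and 0.184 with the block and an estimated correlation), led by the homeobox gene ap (1.34), with 2 rising adjusted over the list alone and 5 with the block, among them the cadherin gene shg (0.58). Without Pc/ph+PTIP replicate 1 that list was not called (adjusted p = 0.075). Polycomb-target regulators were higher (mean 0.18, median 0.03, adjusted p = 0.00217; adjusted p = 0.709 with an estimated correlation), with pnr, cad, croc (1.19), sqz (1.04) and ap rising, 7 adjusted over the list alone, and 0 falling. With the block 9 rose and 1, Sox14, fell by 0.998. That list was not called after cyclic loess (0.0814), in replicates 2 and 3 only (0.378), or without control replicate 2 (0.0513) or Pc/ph+PTIP replicate 1 (0.476). Hox genes (median 0.21, adjusted p = 0.0261; adjusted p = 0.334 with an estimated correlation) were not called with the block (0.202), after cyclic loess (0.231) or in replicates 2 and 3 only (0.442), nor without control replicate 2 (0.0513), control replicate 3 (0.0714) or Pc/ph+PTIP replicate 1 (0.303). DNA damage genes were lower (median -0.22, adjusted p = 0.0172; adjusted p = 0.992 with an estimated correlation), with PolQ (-0.73) and PolZ1 (-0.71) falling under the block, though not in replicates 2 and 3 only (0.216), nor without control replicate 2 (0.0513) or Pc/ph+PTIP replicate 1 (0.146).

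Ribosomal protein genes were called higher than in control (median 0.06, adjusted p = 0.0225; adjusted p = 0.992 with an estimated correlation), with RpS10a rising by 0.47 under the block. That call was lost in the upper range of mean values (0.0798), after cyclic loess (0.484), in replicates 2 and 3 only (0.0784) and without control replicates 2 (0.791) and 3 (0.916), and the direction turned without Pc/ph+PTIP replicate 1 (0.146). Polycomb group genes were called higher (median 0.13, adjusted p = 0.0334; adjusted p = 0.992 with an estimated correlation), with corto rising by 0.57 under the block. Their call was lost in the upper range of mean values (0.196) and without control replicate 1 (0.155), control replicate 3 (0.0803), and Pc/ph+PTIP replicates 2 (0.0904) and 3 (0.0911). Apoptosis and stress genes were lower (median -0.06, adjusted p = 0.0244; adjusted p = 0.421 with an estimated correlation), with ImpL2 (-0.90) and egr (-1.55) falling and DnaJ-1 (0.34) rising under the block, and 6 falling and 2 rising adjusted over the list alone. They were not called as a list with the block (0.110), after cyclic loess (0.157) or in replicates 2 and 3 only (0.158), nor without control replicate 1 (0.748) and Pc/ph+PTIP replicates 2 (0.128) and 3 (0.289). Hemocyte markers were lower (median -0.09, adjusted p = 0.0334; adjusted p = 0.992 with an estimated correlation), with eater (-1.70) and SPARC (-0.58) falling under the block, but not without control replicate 1 (0.0529), control replicate 2 (0.0782), and Pc/ph+PTIP replicates 2 (0.0943) and 3 (0.108).

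Pc/ph+PTIP against Pc/ph knockdown asks whether genes released by Polycomb loss stay high when PTIP is targeted as well. Esp was lower by 3.02 in the cells that also received PTIP dsRNA (-3.02 ± 0.27, SE, n = 3; adjusted p = 0.00148), and nuf (-2.54 ± 0.27), rib (-2.09 ± 0.25), disco-r (-1.95 ± 0.16) and cad (-1.69 ± 0.21) were lower too. The cells in this comparison also differ in their Pc level, as given above, and their Ptip level was lower in replicate 1 only. Other genes that fell were the neprilysin-like gene Nepl9 (-2.15 ± 0.30), Glt (-2.07 ± 0.33), Oat (-1.996 ± 0.19), the signalling regulator Dhit (-1.98 ± 0.23) and Ugt35C1 (-1.75 ± 0.30). Rises were found for CNMa (3.22 ± 0.38), rau (3.20 ± 0.26, adjusted p = 0.00148), Phk-3 (2.85 ± 0.36), fng (2.68 ± 0.29), Cbs (2.58 ± 0.29), amd (2.36 ± 0.34), Smvt (2.11 ± 0.30), Gnmt (1.92 ± 0.19) and the centrosome-related gene Rcd2 (1.83 ± 0.20). Under the replicate block CBP (-3.41 ± 0.73), the phagocytosis receptor gene NimC1 (-3.27 ± 0.51), Cyp28a5 (-3.07 ± 0.22), the deadenylase gene cu (-2.51 ± 0.41), Optix (-2.40 ± 0.44) and eater (-2.27 ± 0.23) fell as well. Dfd differed by -0.34 ± 0.15 and was not called, nor with the block (adjusted p = 0.0715).

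Between Pc/ph+PTIP and Pc/ph cells limma called 56 probe sets, 24 higher and 32 lower, and 696 had an unadjusted p under 0.05. The replicate block gave 1033, 544 higher and 489 lower, with 202 changed at least 2-fold (79 higher, 123 lower), and all 56 were among them. Replicates 2 and 3 alone gave 2941, 1636 higher and 1305 lower, with 71.6% of the same sign in replicate 1. Leaving out an array gave 36 calls each without control replicates 2 and 3 and without PTIP replicate 3, 27 and 25 without Pc/ph replicates 2 and 3, and 28 and 25 without Pc/ph+PTIP replicates 2 and 3. Of the 24 named genes 15 kept their call without any single array, among them CNMa, rau, fng, Cbs, Esp, nuf, rib, Oat, disco-r and cad.

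Hemocyte markers were lower in Pc/ph+PTIP than in Pc/ph cells (median -0.16, adjusted p = 2.64e-06; adjusted p = 0.712 with an estimated correlation, and 0.0456 with the block and an estimated correlation). Glt fell without the block, and 2 members fell adjusted over the list alone. With the block 9 fell and 1, the growth factor receptor gene Pvr (0.53), rose, and 15 fell and 3 rose adjusted over the list alone. The cell cycle list was higher (median 0.31, adjusted p = 3.77e-06; adjusted p = 0.712 with an estimated correlation), with 4 members rising under the block, 14 adjusted over the list alone, among them CycB (0.50) and Orc2 (0.52). Polycomb-target regulators were lower by the test and the mean (-0.14), with a median of 0.00 (adjusted p = 0.00377; adjusted p = 0.712 with an estimated correlation). In that list peb (-1.54), disco (-1.59), pnr (-1.42) and cad fell and 0 rose, against 9 falling and 2 rising adjusted over the list alone, and with the block 10 fell while croc (0.84) and ap (0.82) rose. The list was not called after cyclic loess (0.0596), nor without Pc/ph replicate 1 (0.116) or Pc/ph+PTIP replicates 2 (0.131) and 3 (0.227). Ribosomal protein genes were higher (median 0.08, adjusted p = 0.00249; adjusted p = 0.980 with an estimated correlation), with RpS10a (0.55) and RpS5b (0.68) rising under the block, but not after cyclic loess (0.0596) or without Pc/ph replicates 2 (0.842) and 3 (0.482), and the direction turned without Pc/ph+PTIP replicate 1 (0.448). Apoptosis and stress genes were lower (median -0.11, adjusted p = 0.0371; adjusted p = 0.712 with an estimated correlation), with 6 members falling and 1 rising under the block, and 7 and 2 adjusted over the list alone. These include the metallothionein gene MtnA (-1.26), ImpL2 (-0.80) and, rising, Gadd45 (0.53). The list was not called in the upper range of mean values (0.0876), after cyclic loess (0.141), or without PTIP replicate 1 (0.0536), Pc/ph replicate 1 (0.575) or Pc/ph+PTIP replicates 2 (0.287) and 3 (0.407). In the humoral immunity list PGRP-LB rose by 1.42 and PGRP-LA fell by 1.18, and the list was not called (adjusted p = 0.476).

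Pc/ph+PTIP against PTIP knockdown asks what targeting Pc and ph adds where PTIP is already targeted. Pc itself was not called lower in this comparison (-0.68, adjusted p = 1.000 without and with the block) or in Pc/ph+PTIP against control cells (-0.74, adjusted p = 1.000, and 0.0601 with the block). CNMa rose by 4.53 ± 0.38 (SE, n = 3; adjusted p = 0.00143), cad by 3.01 ± 0.21, pnr by 2.51 ± 0.17 and rib by 2.10 ± 0.25, and CG2233 changed by -1.05 ± 0.13. The Dfd difference of 0.71 ± 0.15 was not called (adjusted p = 0.990, and 0.0507 with the replicate block). Limma called 6 probe sets, 5 higher and 1 lower, both without and with the replicate block, and 117 and 778 had an unadjusted p under 0.05. The remaining call was on a probe set with several symbols. There were 61 calls in replicates 2 and 3 alone, 43 higher and 18 lower, with 85.2% of the same sign in replicate 1. After quantile normalization 3 were higher and 0 lower. The count was 3 without control replicates 2 and 3, without PTIP replicate 3, without Pc/ph replicate 3 and without Pc/ph+PTIP replicates 1 and 2. CNMa, cad and pnr kept their call without any single array.

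In that comparison 8 lists were called higher. Apoptosis and stress genes had a median of 0.12 (adjusted p = 5.38e-04; adjusted p = 0.0786 with an estimated correlation). Epithelial markers had a median of 0.08 (adjusted p = 5.38e-04; adjusted p = 0.0492 with an estimated correlation), and Hox genes a median of 0.29 (adjusted p = 6.20e-04; adjusted p = 0.0492 with an estimated correlation). With the block and an estimated correlation these last 2 lists were not called (adjusted p = 0.109 and 0.175). JAK/STAT genes (10 genes, median 0.12), hemocyte markers (median 0.07) and humoral immunity genes (median 0.04) each had an adjusted p = 0.00174, and adjusted p = 0.471, 0.713 and 0.471 with an estimated correlation. Polycomb group genes had a median of 0.08 (adjusted p = 0.00222; adjusted p = 0.762 with an estimated correlation). Polycomb-target regulators had a mean of 0.12 and a median of 0.00 (adjusted p = 0.00271; adjusted p = 0.713 with an estimated correlation), with pnr and cad rising, 4 rising adjusted over the list alone, and no call with the block (adjusted p = 0.0927). No member of the other 7 lists passed. Adjusted over the list alone, 1 Hox gene and 1 epithelial marker rose. Without PTIP replicate 3 the apoptosis, epithelial, Hox, JAK/STAT, hemocyte and immunity lists were not called, at 0.0603, 0.0585, 0.0513, 0.0585, 0.0585 and 0.0585. Without Pc/ph+PTIP replicate 1 they were at 0.699, 0.633, 0.185, 0.173, 0.173 and 0.818. In replicates 2 and 3 only the apoptosis and immunity lists were not called (0.0611 and 0.111). The Polycomb group list was lost without PTIP replicate 1 (0.710), in the upper range of mean values (0.231), after cyclic loess (0.0707) and in replicates 2 and 3 only (0.222). The Polycomb-target list was lost without PTIP replicate 3 (0.725), and its direction turned without PTIP replicate 2 (0.954) and Pc/ph+PTIP replicate 1 (0.699).

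The interaction tests whether the PTIP effect differs between Pc/ph and control cells. Esp was the single call, at -3.93 ± 0.38 (SE, n = 3; adjusted p = 0.0166, and 0.00299 with the replicate block), and 160 probe sets had an unadjusted p under 0.05. It was not called without control replicates 1, 2 and 3, PTIP replicates 2 and 3, Pc/ph replicates 2 and 3 or Pc/ph+PTIP replicates 2 and 3, where limma called 0 probe sets and 164, 121, 155, 180, 134, 140, 141, 123 and 120 had an unadjusted p under 0.05. There were 4 calls without Pc/ph replicate 1 and 7 without Pc/ph+PTIP replicate 1. After quantile normalization the 1 call was a rise on another probe set. Under the replicate block 35 probe sets passed, 20 higher and 15 lower. Among these the genes that rise after Pc/ph loss had negative interactions, at -2.41 ± 0.24 for rib, -1.88 ± 0.15 for disco-r, -1.78 ± 0.28 for cad, -1.50 ± 0.12 for peb, -1.49 ± 0.20 for disco and -1.49 ± 0.18 for pnr. In control cells the PTIP effect on these genes was 0.33, -0.06, 0.09, -0.04, -0.10 and 0.06, so most of each interaction is the difference between Pc/ph+PTIP and Pc/ph cells. In Pc/ph+PTIP cells Pc was also higher than in Pc/ph cells, by 1.59. The interaction of Pc itself was 1.65 ± 0.28 with the block and was not called by limma (adjusted p = 0.0657 with the block). These interactions can therefore not be assigned to PTIP rather than to the Pc level. The control means of disco-r (5.14), cad (5.21), peb (5.24), disco (4.83) and pnr (5.38) are near the Y-linked probe sets, which limits how large a fall in control cells could be measured. For rib, at 5.84 in control replicate 1 where the highest Y-linked value was 5.15, this limit is weaker in that array only. In control replicates 2 and 3 rib was at 5.42 and 5.34, below the highest Y-linked values of 5.47 and 5.49. Positive values were found for CNMa (3.26 ± 0.40), Cbs (2.51 ± 0.36), fbp (1.64 ± 0.21), Kank (1.57 ± 0.15), fru (1.24 ± 0.15) and Mal-A5 (1.19 ± 0.15). For fbp the PTIP effect was larger in control than in Pc/ph cells. The Dfd interaction of -0.73 ± 0.21 was not called (adjusted p = 1.000, and 0.102 with the block). There were 264 calls in replicates 2 and 3 alone, 142 higher and 122 lower, with 79.2% of the same sign in replicate 1.

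Polycomb-target regulators had lower interaction values than other genes (mean -0.20, median -0.07, adjusted p = 7.56e-09; adjusted p = 0.326 with an estimated correlation), and the block kept the call (adjusted p = 5.16e-05). For this list too, PTIP and the Pc level cannot be told apart. Of its members 0 passed in limma without the block, 4 fell adjusted over the list alone, and 5 fell with the block. Without PTIP replicate 1 the list was not called (adjusted p = 0.493). Apoptosis and stress genes had higher interaction values (median 0.05, adjusted p = 0.0393; adjusted p = 0.326 with an estimated correlation), not with the block (0.123), in the upper range of mean values (0.0681) or after cyclic loess (0.412), nor without control replicate 1 (0.913), PTIP replicate 3 (0.263), Pc/ph replicate 3 (0.342) or Pc/ph+PTIP replicate 1 (0.794), and in replicates 2 and 3 only the direction turned (0.891). DNA damage genes (median 0.15) and Trithorax group genes (27 genes, median 0.10) were not called without the block (adjusted p = 0.0624 for both) and were called with it (adjusted p = 0.0129 and 0.0354; 0.633 for both with the block and an estimated correlation). Both also passed with all probe sets of the members. The DNA damage list passed without control replicate 3 (0.0235), PTIP replicate 2 (8.76e-04), Pc/ph replicates 2 (0.0329) and 3 (0.0231) and Pc/ph+PTIP replicate 1 (0.0118). The Trithorax list passed without control replicate 1 (0.00457), PTIP replicate 2 (0.0226) and Pc/ph replicates 2 (0.0376) and 3 (0.0231).

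Genes that rise after Pc/ph loss were also measured on arrays that had no part in choosing them. Over 9 combinations, with 7 to 31 probe sets chosen, their mean difference between the left-out Pc/ph and control arrays was 2.94 (range 2.09 to 3.55). In Pc/ph+PTIP against control cells it was 1.22 (range 0.71 to 1.60), so the mean difference between Pc/ph+PTIP and Pc/ph was -1.72 (range -1.999 to -1.34). Probe sets chosen as lower, 1 to 8 per combination, gave -2.50 for Pc/ph against control, -0.57 for Pc/ph+PTIP against control and 1.92 (range 0.80 to 2.81) between these. Combinations with 1 probe set gave 2.21 to 2.81, and those with 3, 5 and 8 gave 0.80, 0.92 and 0.82. The mean of 1.92 thus rests mostly on single probe sets. With the 100 genes of largest moderated t the difference between Pc/ph+PTIP and Pc/ph was -0.66 (range -0.79 to -0.49) for the higher side and 0.27 (range -0.15 to 0.46) for the lower side. With the replicate block and same-number arrays it was -0.97 (range -1.37 to -0.46) and 0.41, and after cyclic loess it was 0.62 on the lower side.

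The PTIP effects with and without Pc/ph dsRNA rest on different arrays, and across 18769 probe sets they correlated at r = 0.713 (Spearman 0.537), with a slope of 0.703. Of the 1224 probe sets called in PTIP cells with the replicate block, 1174 (95.9%) had the same sign in Pc/ph cells, and 593 were called in both, against 33.4 under independence. By replicate number the correlation was 0.620, 0.605 and 0.691, and in replicates 2 and 3 together 0.721. The Pc/ph effects with and without PTIP dsRNA correlated at r = 0.468 (Spearman 0.272), with a slope of 0.290. Of 287 calls 238 (82.9%) had the same sign and 4 were called in both, against 0.0436 under independence. By number this correlation was 0.322, 0.331 and 0.398, and in replicates 2 and 3 together 0.427. Probe sets are not independent replicates, so these correlations carry no p-value.

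**Figure D2:**
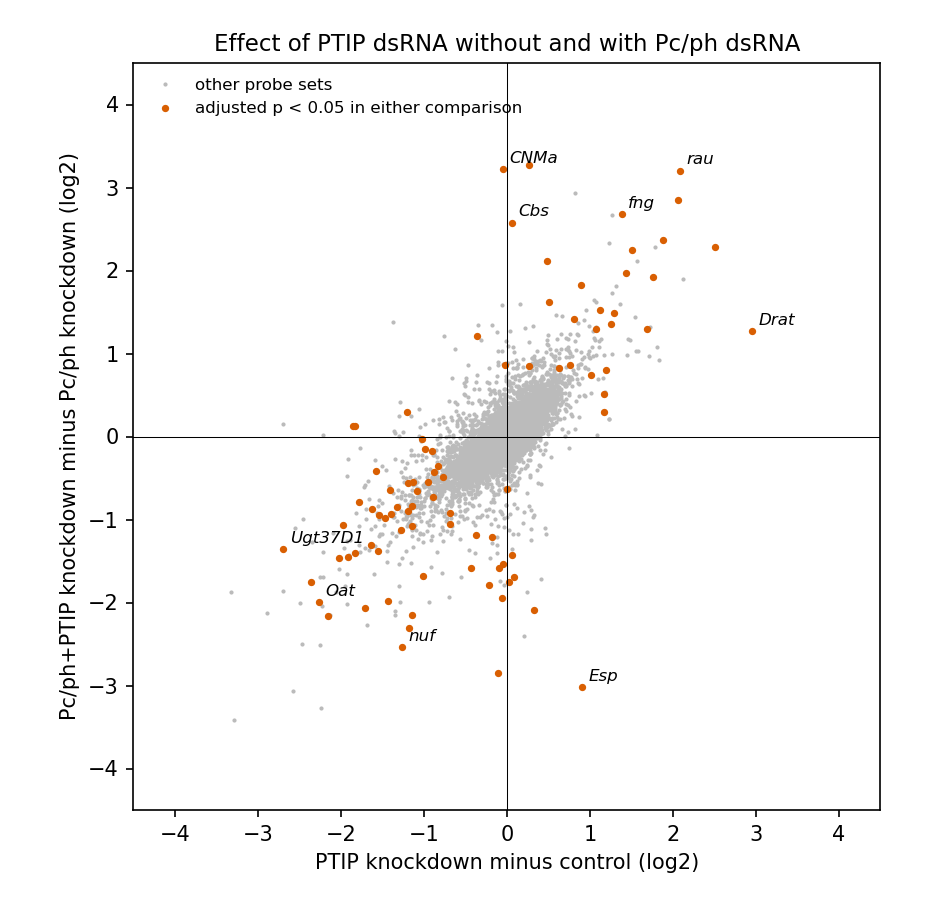
PTIP effect on each probe set in log2 units, in control cells on the horizontal axis and in Pc/ph cells on the vertical axis, with probe sets at an adjusted p under 0.05 in either comparison in orange. The correlation across probe sets is 0.713, and Esp is at -3.02 and CNMa at 3.22 on the vertical axis.

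Calls shared by the PTIP and Pc/ph knockdowns, which use the same control arrays, were 0 higher and 4 lower. With the replicate block 14 were shared as higher and 62 as lower, against 3.62 and 5.85 under independence, and 22 had opposite signs. The effects correlated at 0.1903 across probe sets. Over 100 simulations, unchanged groups with shared controls gave a mean of 0.5002 without the block and 0.5007 with it. Shared controls alone give such a value and real changes can alter it, so this comparison does not show whether the effects are alike. The covariance of 0.0127 lay below the simulated 0.0493 without the block and above the simulated 0.0086 with it. The simulation without the block drew the replicate 1 batch as independent noise in each array. In the real data that batch is balanced between the groups, so the 0.0493 is no fair reference and nothing is concluded from it. Simulated shared calls averaged 0.01 higher and 0 lower without the block, and 0 in either direction with it. Unchanged groups give almost no calls at all, so these averages do not show how many calls changed groups would share through their controls.

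Several lists were called in none of the 6 comparisons by camera, with or without the block. For Notch targets (11 genes) 1 member passed under the block, E(spl)mbeta-HLH at -0.77 in Pc/ph cells. RNA interference genes (10 genes) held a fall of Dcr-2 by 0.89 and a rise of Tudor-SN by 0.33 in PTIP cells under the block. The germline list (21 genes) held a rise of bam (0.83) and falls of stau (-0.87), bgcn (-0.61) and aub (-0.57) there. In the muscle list (15 genes) the titin-family gene bt fell by 0.92 in PTIP cells under the block, and in Pc/ph+PTIP against control cells the list had a median of 0.04 and a mean of -0.04. Ecdysone response genes (26 genes) held, in PTIP cells under the block, rises of MsrA (1.36), Cyp18a1 (0.75) and dor (0.54) and falls of ImpL2 (-1.50), Sox14 (-0.80) and Kr-h1 (-0.71). No member of the neuronal (18 genes) or fat body and gut (14 genes) lists passed in limma in any comparison with or without the block, and adjusted over each of these lists alone 0 passed.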

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

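In this part the tests of a mislabelled array, of the Pc level, of a need for PTIP, of a response to any dsRNA, of another target of the PTIP dsRNA and of regrouping within replicate numbers without the block were chosen only after the result was seen.

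The results picked out here are differences between the PTIP effect in Pc/ph cells and the PTIP effect in control cells, each by the interaction test in limma. Esp was the 1 probe set that passed, at -3.93, and with the replicate block 35 passed. Among these 35, genes called higher in Pc/ph cells with the block had negative values, with rib at -2.41, disco-r at -1.88, cad at -1.78, peb at -1.50, disco at -1.49, pnr at -1.49 and gsb-n at -1.14. Such genes were also Drat (-1.68), CG44251 (-1.25), the virus-induced gene vir-1 (-1.10) and the noncoding RNA gene lncRNA:alphagamma-element:CR32865 (-0.99). Genes called lower in Pc/ph cells with the block had positive values, with Cbs (2.51), CG4269 (2.23), CG14990 (1.70), fbp (1.64), Kank (1.57), CG9164 (1.498), CG4914 (1.40), CG31337 (1.33), fru (1.24), Mal-A5 (1.19) and CG12290 (1.15), and CNMa, not called there, was at 3.26. The Pc/ph and control arrays enter both tests, so opposite signs in the 2 are favoured by design. In control cells the PTIP effect was 0.33 for rib and between -0.10 and 0.09 for disco-r, cad, peb, disco, pnr and gsb-n, so most of these values is the difference between Pc/ph+PTIP and Pc/ph cells. Control means near the Y-linked probe sets limit how large a fall could be measured for these last 6 genes. The same limit holds for rib in control replicates 2 and 3. For Drat, CG4269, CG14990, fbp and CG9164, by contrast, the PTIP effect was larger in control than in Pc/ph cells. Pc was higher by 1.59 in Pc/ph+PTIP than in Pc/ph cells, so none of these interactions can be assigned to PTIP rather than to the Pc level. Among the gene lists, the interaction was called for Polycomb-target regulators (adjusted p = 7.56e-09, and 5.16e-05 with the block) and for apoptosis and stress genes (adjusted p = 0.0393), and with the block also for Trithorax group genes (adjusted p = 0.0354) and DNA damage genes (adjusted p = 0.0129), both at 0.0624 without it. Without PTIP replicate 1 the Polycomb-target list was not called (adjusted p = 0.493), and none of these lists was called with an estimated correlation.

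Other groupings of the arrays bear on the interaction. Of 100 regroupings over all arrays, the real one included, 4 gave at least the 1 probe set called without the block (highest other 10421). These ignore the replicate number and mostly unbalance the replicate 1 batch, which the real groups balance, so their share excludes nothing. The highest put the replicate 1 arrays of control, Pc/ph and Pc/ph+PTIP together, so it follows the batch and points to that structure of the arrays rather than to the knockdowns. Of 100 regroupings within replicate numbers, 3 gave at least the 1 probe set without the block (highest other 4) and 4 at least the 35 with it (highest other 456). Such regroupings also mix the PTIP and Pc/ph knockdowns between groups. Their effects then enter the spread or the regrouped contrast. The shares therefore do not test whether an interaction is absent, and they exclude nothing. The highest put PTIP replicates 2 and 3 and Pc/ph replicate 1 together, and what gave its 456 calls was not tested. The call on Esp was lost in 9 of the 12 fits that left out 1 array, which have no block and unbalance the replicate 1 batch. For the number of lists called, 87 of 100 regroupings gave at least the real 2 (highest other 9), so for the lists chance is not excluded.

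The first pattern weighed is that the replicate 1 arrays of all 4 groups stand apart. On the first principal component 4 of the 4 lie below all others. By itself 1 mislabelled array would not set 4 apart, but this count restates the pattern and is no separate test of the labels. A difference in overall scale or spread is argued against as the whole source, since 52.0% of the probe sets still differed after quantile normalization, against 81.7% as deposited. A step after the RNA was made remains a candidate source, since the hybridisation control probe sets, which are added to the labelled RNA, differed by 0.530 between replicate 1 and the others and by 0.142 between replicates 2 and 3. No biological explanation was tested, since the labels give no group that parts replicate 1 from the others.

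The second pattern is that genes that rose after Pc/ph knockdown rose less when PTIP dsRNA was added. Genes picked for chance values in the Pc/ph arrays are argued against by the arrays left out of the choice, where the mean difference was -1.72 with an SD of 0.28 over the combinations. The difference was smaller with the 100 genes of largest moderated t (-0.66, SD 0.11) and with the replicate block and same-number arrays (-0.97, SD 0.46 over 3 combinations), where it lay only just over 2 SD below 0. The combinations share arrays, so these SDs are not sampling errors. In every combination of these settings the difference lay below 0. Weaker depletion of Pc in the Pc/ph+PTIP arrays is a candidate explanation, since Pc was higher there by 1.59 under the replicate block. A need of the genes for PTIP to rise stays open as well, since 0 of the Pc/ph+PTIP arrays had a Pc value within the range of the Pc/ph arrays, so these explanations cannot be told apart for these genes. Some genes lie outside this pattern. CNMa, bero, Idgf1 and CG13506 were higher in Pc/ph than in control arrays of each number and higher still in Pc/ph+PTIP arrays, the latter by 3.22, 1.30, 0.71 and 1.22, of which the block called the first only (adjusted p = 2.22e-04, 0.150, 0.556 and 0.308).

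The third pattern is that probe sets changed after PTIP dsRNA in the same direction with and without Pc/ph knockdown. A response to the mere presence of any dsRNA is argued against as the whole source. The effects with and without Pc/ph dsRNA correlated at 0.713, and the Pc/ph cells had received dsRNA on both sides of that comparison. Both effects add a dsRNA, however, so a response to the amount or number of dsRNAs could give such a correlation and stays open. The replicate 1 arrays alone are argued against by replicates 2 and 3, where the correlation was 0.721. Loss of PTIP and another target of the PTIP dsRNA both stay open, since in 0 of the 6 arrays with PTIP dsRNA did Ptip lie more than 1 log2 below the same-numbered array with the same Pc/ph treatment and no PTIP dsRNA. In Pc/ph+PTIP replicates 2 and 3 Ptip lay above that array, at 8.06 and 8.41 against 8.01 and 8.29. Against control, Pc/ph+PTIP replicate 1 was at -1.01.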

How the results depend on the processing

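The fits to replicates 2 and 3 only and to replicate 1 only, the batch term, the alternatives that combine the replicate block with another choice and the block with same-number arrays were chosen only after the data were seen. For the values below, unless a reason is stated, the cause was not tested. Fits without the block that leave out 1 array, for genes and lists, unbalance the replicate 1 batch. They can therefore carry part of that batch difference.

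The replicate block, which takes the difference between replicates out of the spread, gave 1224 calls for PTIP against control, 287 for Pc/ph, 1046 for Pc/ph+PTIP, 1033 for Pc/ph+PTIP against Pc/ph and 35 for the interaction, and 76 calls shared by PTIP and Pc/ph. A batch term for replicate 1 gave 1494, 364, 1306, 1294 and 53 in the first order. Quantile normalization gave 465, 81, 429 and 367 in the 4 pair comparisons named, and 3 for Pc/ph+PTIP against PTIP. Cyclic loess gave 380, 90, 362, 274 and 3 in those 5, and 0 for the interaction (345 at an unadjusted p under 0.05 in limma). Array weights gave 2899, 851, 2514, 2799, 101 and 246. Fits to the 6 arrays of a comparison, with fewer arrays to estimate the spread, gave 3, 20, 11, 18 and 0 (89 at an unadjusted p under 0.05 in the last). Replicates 2 and 3 only gave 2630, 1099, 2205, 2941, 61 and 264, and with the replicate block 2566, 1066, 2194, 2925, 67 and 261. A variance trend gave 3 for the interaction.

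Leaving out each array in turn gave 0 to 80 calls for PTIP against control, 20 to 56 for Pc/ph, 10 to 103 for Pc/ph+PTIP, 25 to 72 for Pc/ph+PTIP against Pc/ph, 3 to 7 against PTIP and 0 to 7 for the interaction. The fewest came without control replicate 2 (605 at an unadjusted p under 0.05), Pc/ph replicate 3, control replicate 3, Pc/ph+PTIP replicate 3, control replicate 2 and control replicate 1 (164), among others. With the replicate block the ranges were 475 to 1699, 134 to 477, 377 to 1563, 333 to 1561, 4 to 17 and 9 to 80. Their lowest counts came without PTIP replicate 3, control replicate 2, Pc/ph+PTIP replicate 3, and Pc/ph+PTIP replicates 2, 2 and 3. Shared calls ranged from 0 to 6, against 4.

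Gene lists called numbered 5, 5, 9, 5, 8 and 2 in the order of comparisons. With an estimated correlation they were 0, 0, 1, 0, 2 and 0, and with the replicate block and an estimated correlation 0, 0, 0, 1, 0 and 0. All probe sets of the members gave 5 for the interaction. The upper range of mean values, with 18 lists testable, gave 3, 3 and 1 for PTIP, Pc/ph and the interaction. Cyclic loess gave 5 for Pc/ph+PTIP against control, 3 against Pc/ph and 1 for the interaction. Replicates 2 and 3 only gave 4 for Pc/ph+PTIP against control and 1 for the interaction. Leaving out single arrays gave 3 to 7, 3 to 8, 4 to 9, 3 to 5, 1 to 10 and 1 to 7.

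Directions turned in few results. The adjusted p of the ribosomal protein list lay between 7.58e-11 and 0.999 for PTIP against control, 6.98e-12 and 0.916 for Pc/ph+PTIP against control and 1.67e-15 and 0.842 against Pc/ph as single arrays were left out, and it turned to lower at 0.473 without PTIP replicate 1 and at 0.146 and 0.448 without Pc/ph+PTIP replicate 1. That of the Polycomb-target list in Pc/ph+PTIP against PTIP lay between 5.41e-14 and 0.954, with the direction turned at 0.954 without PTIP replicate 2 and 0.699 without Pc/ph+PTIP replicate 1. The apoptosis list interaction turned at 0.891 in replicates 2 and 3. The kto difference in PTIP cells, called lower with the replicate block only, ran from -0.57 to 0.0075, the latter without PTIP replicate 1.

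Genes that rise after Pc/ph loss differed between Pc/ph+PTIP and Pc/ph by -1.72 on arrays left out of the choice, and by -0.66 for the top 100 genes, -1.34 after cyclic loess and -0.97 with the replicate block and same-number arrays. Genes that fall there differed by 1.92, and by 0.27, 0.62 and 0.41 in the same order, and by 2.38 in the upper range of mean values. The 1.92 and 2.38 rest mostly on combinations with 1 probe set. The PTIP effects correlated at 0.713, at 0.620 in replicate 1 only, and at 0.567 to 0.708 without single arrays, lowest without Pc/ph+PTIP replicate 1. The Pc/ph effects correlated at 0.468, at 0.322 in replicate 1, 0.427 in replicates 2 and 3, 0.537 in the upper range of mean values and 0.220 to 0.467 without single arrays, lowest without Pc/ph+PTIP replicate 1.

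Of 351 results for named genes, 115 were called without the block. The replicate block, array weights and replicates 2 and 3 only kept all 115, quantile normalization 88, cyclic loess 90, a variance trend 94, and fits to 6 arrays 34 of 114. Leaving out 1 array kept 53 to 101. Signal over background limits genes near the range of the Y-linked probe sets, whose highest values were 5.11 to 5.57: for cad and pnr, whose control means lie there, the fall below control that could be measured is limited.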

Other observations

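The tests of symbol families were chosen only after the genes were seen, and so was the control probe set described last.

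Genes that fell with PTIP dsRNA include members of detoxification families, grouped here by the stem of their symbols and tested with Fisher's exact test (one-sided) over 49 stems. That test takes genes as independent, while members of a family can vary together over the arrays, so its p-values may be too small. Among genes called lower in PTIP cells were 3 of 35 Ugt genes, Ugt37D1, Ugt35C1 and Ugt302C1, against 0.0964 expected (adjusted p = 0.00575), and the same 3 fell in Pc/ph+PTIP against control (adjusted p = 0.00246). With the replicate block 12 of 83 Cyp genes (3.89 expected, adjusted p = 0.0112) and 6 of 13 GstE genes (0.609 expected, adjusted p = 6.51e-04) fell in PTIP cells, while the Ugt family did not pass there (6 genes, 1.64 expected, adjusted p = 0.0852). Against control, 11 Cyp and 6 Ugt genes fell in Pc/ph+PTIP cells (adjusted p = 0.00747 and 0.0311), and against Pc/ph cells 4 GstE and 6 Ugt genes fell (adjusted p = 0.0210 for both). GstE against control (3 genes, adjusted p = 0.156) and Cyp against Pc/ph cells (7 genes, adjusted p = 0.306) did not pass. Without the block, Cyp (2 of 83, adjusted p = 0.534) and GstE (1 of 13, adjusted p = 0.576) did not pass in PTIP cells. Nor did GstE in Pc/ph+PTIP against control (1 gene, adjusted p = 0.657) or Ugt against Pc/ph cells (2 genes, adjusted p = 0.126). Not all members moved together: Cyp12d1-d rose in PTIP cells, and the Ugt median was -0.03 as deposited, -0.05 after quantile normalization and -0.06 after cyclic loess. The GstE median was -0.45, -0.40 and -0.46, with 11, 10 and 11 of 13 below 0. In the other direction 5 of 21 Polr genes, which encode RNA polymerase subunits, were called higher in Pc/ph+PTIP than in Pc/ph cells with the block (0.799 expected, adjusted p = 0.0470), with medians of 0.25, 0.28 and 0.26 under the 3 scalings. The family did not pass with the block in PTIP cells (4 genes, adjusted p = 0.258) or in Pc/ph+PTIP against control (1 gene). In Pc/ph against control cells 17 of 21 lay below 0 as deposited, with a median of -0.13.

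Neighbouring genes were called higher together after Pc/ph knockdown more often than random draws of as many genes. The 18 genes called higher held 1 pair of neighbours, disco-r and disco (mean of the random draws 0.026, one-sided permutation p = 0.026). Under the block 110 genes held 6 pairs against a mean of 1.00 (95th percentile 3, permutation p = 0.001, the smallest the draws can give). These were disco-r and disco, NimB5 and He, and a run of CG5888, Idgf1, Idgf2, Idgf3 and dac. That neighbouring genes rise together is thus a hypothesis that 1 pair and, with the block, 6 pairs leave open, and duplicated genes such as the Idgf genes may share sequence on the arrays, which was not tested. Genes called lower in Pc/ph cells held 0 pairs without the block (13 genes, permutation p = 1) and 1 pair with it (130 genes, mean 1.403, permutation p = 0.762). In PTIP cells, with the block, genes called lower held 64 pairs against a mean of 26.2 (95th percentile 34, permutation p = 0.001) and genes called higher 19 against 14.3 (permutation p = 0.135). The draws treated all 11893 placed genes alike, including those near background, which can hardly be called lower. Neighbours of 1 family, such as GstE6, GstE7 and GstE9, were also called lower there. The 64 pairs are thus not shown to reflect position as such.

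Single genes of other lists passed with the replicate block only. In PTIP cells the interleukin-receptor-like gene et fell by 1.44 and its relative dome rose by 0.49. The demethylase gene Utx fell by 0.74 and the chromatin remodelling gene mor rose by 0.36 there, while tna fell by 0.66 in Pc/ph cells. In Pc/ph+PTIP against Pc/ph cells wds rose by 0.67 and p53 by 0.52.

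For the 5 pair comparisons, each of 3 against 3 arrays, the splits are too few (10, or 4 with 1 array of each number per group) for a share under 0.05. In each, the real split was the 1 split with as many probe sets called (51, 37, 51, 56 and 6, with a highest other of 0), and with the replicate block it was 1 of 4 (1224, 287, 1046, 1033 and 6, with a highest other of 0). The other splits mix arrays of both groups, so a difference between the groups enters their spread. Without the block some also unbalance the replicate 1 batch. Their 0 calls were thus likely in advance and lend the real counts no support. For the number of lists called, 3, 4, 1, 4 and 1 of the 10 splits gave at least the real 5, 5, 9, 5 and 8, with a highest other of 5, 6, 7, 8 and 6.

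Among the 183 control probe sets, 1 was present in some arrays and near background in others. Its log2 values were 10.73, 13.74 and 13.77 in control, 5.37, 13.22 and 12.43 in PTIP, 5.37, 13.004 and 13.04 in Pc/ph, and 5.23, 5.73 and 5.29 in Pc/ph+PTIP replicates 1, 2 and 3. What this probe set detects is not given in the sources used here, and whether its signal comes from material added to the cells was not tested. Its values differ between groups and within them, so they limit how far the groups can be taken to differ in the named targets only.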
